A study of Homo sapiens with 12 samples.

How the data were processed

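RNA from MV-4-11 cells was sequenced in 4 groups of 3 libraries: DMSO, HPA-12, crenolanib and the combination of both compounds. The series description gives 48 h for the 3 treated groups and no time for DMSO. The labels give total RNA as the material and no doses. They number the libraries of each group without saying whether these came from separate cultures, so the p-values below measure the spread between these libraries, which may be technical only.

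The deposited table holds FPKM, fragments scaled by gene length and by library size, computed by the authors, with 1 column per library (per the file headers). The read alignment, the counting, the genome build and the annotation are not given in the sources used here. The table lists 20036 genes by Ensembl identifier, of which 2509 were at 0 in every library. A symbol was found for 20011 of them, and each of the 12 value columns was matched to its library by name, with 0 columns left over. The sample titles and the value columns spell the short name of crenolanib in 2 ways, which were read as the same compound.

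Read counts were not used here. Depth was estimated as the number of reads at which the most low FPKM values of a library, multiplied by gene length, came out as whole reads, with lengths taken from GENCODE release 29, which held 19852 of the identifiers. Of the values under 20 estimated reads, the share that came out whole within 0.01 read was 38.8% on average in the DMSO libraries and 30.7% in the combination libraries. These depths are therefore estimates, and lengths used by the authors may differ from those used here. Shares of mitochondrial transcripts were taken over the 13 mitochondrially encoded protein genes in the table.

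The design fixed a count-based test in case the file held counts and a limma test in case it held normalised values. Since the values were FPKM, the limma branch was used. Genes with at least 1 FPKM in at least 3 of the 12 libraries were kept, which left 11149. Log2 of FPKM plus a pseudocount of 1 was fitted with limma 3.58.1 in R 4.3.3, with statmod 1.5.0 for the robust step, as 1 factor with 4 levels and empirical Bayes moderation with a mean-variance trend. Contrasts were HPA-12 vs DMSO, crenolanib vs DMSO, combination vs DMSO, combination vs crenolanib, combination vs HPA-12, and the interaction, defined as combination minus crenolanib less HPA-12 minus DMSO. P-values are two-sided limma values adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. A gene is said to have risen, fallen or changed only below that threshold. All fold changes are log2 differences on the FPKM plus 1 scale with the standard error of the fit, and this scale understates the changes of genes with low FPKM.

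Before the data were examined, 30 gene lists with 621 members were fixed, of which 620 were in the table. Of these lists, 28 had at least 5 tested members and were tested with limma's camera against all other tested genes, with a preset correlation between genes of 0.01 and adjustment over the lists. The test was repeated with a correlation estimated from the data, and with fry, which asks whether the members of a list move one way on balance and compares them with no other genes. For each list the members that passed are given over all genes tested and, where the count differs, "adjusted over the list alone". The lymphoid and the stromal and epithelial marker lists had too few tested members and are given as values only.

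Genes named in the text follow a rule fixed at the same time. It takes the 8 most raised and the 8 most lowered genes per comparison among those that passed, with a symbol, a mean of at least 5 FPKM over the 12 libraries and no overlap between the groups. For combination vs HPA-12 and for the interaction it takes 5 each way, without the overlap condition for the interaction. It adds HSPA5, ATF6, DDIT3, ATF4, XBP1, CERT1 and FLT3 in every comparison, and up to 4 members with the smallest p of each list that passed. Some genes that the rule takes are not given, and none was put in their place. Members named outside this rule are stated as chosen after their values were seen.

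The gene test was tested on simulated data with the means and spreads of these libraries, 11149 genes, and 100 genes changed at each of 2 sizes. The 12-library fit recovered 77% of the changes of 1 log2 unit for HPA-12 vs DMSO and 72% for crenolanib vs DMSO, with 0 and 3 false calls. At 0.5 log2 units it recovered 30% in both, so most changes of that size were missed. Combination vs DMSO gave 87% with 276 false calls, 2.52% of the unchanged genes. Combination vs crenolanib gave 86% with 393 false calls (3.59%), and combination vs HPA-12 gave 74% with 329 false calls (3.00%). At 0.5 log2 units these 3 comparisons recovered 41%, 50% and 49%. False calls made up 68.1%, 74.3% and 72.8% of all their calls, shares that hold for the few genes changed in these simulations. The fit uses 1 spread per gene for all 4 groups, and the combination libraries varied more than the others. A fit of the 2 compared groups only gave 14, 13 and 19 false calls in these 3 comparisons. It recovered 38%, 31% and 35% of the changes of 1 log2 unit. With 1 weight per group there were 40, 41 and 59 false calls, and 62%, 56% and 52% were recovered. For HPA-12 and crenolanib vs DMSO these fits gave more false calls, 9 and 16 and then 35 and 35. In a separate simulation for HPA-12 vs DMSO, only the mitosis list was moved, by 0.5 log2 units. Camera found it with an adjusted p of 3.4e-110, and 0 of the other 27 lists were called. That simulation had no correlation between genes, no shift of all genes and no other changed genes. It therefore cannot tell how often lists are called falsely where these are present.

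Alternative settings chosen in advance were pseudocounts of 0.1 and 5, no filter on low values, a mean of at least 5 FPKM, a fit of the 2 compared groups only, the library number as a replicate block, an absolute log2 fold change over 1, each library left out in turn, the estimated correlation and fry. Chosen after the data were seen were rescaling by the median ratio, by the upper quartile and by the total without mitochondrial genes, 1 weight per group, genes above 0 in all 12 libraries, a fit without the combination libraries, and the comparison of crenolanib with HPA-12. The alternatives planned for counts were not run, since the table holds no counts. Tables were prepared with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.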

Results

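MV-4-11, a human acute myeloid leukaemia line that depends on a mutated FLT3 receptor and carries a KMT2A fusion, was profiled by RNA sequencing in 4 groups of 3 libraries. The 3 treated groups were sampled at 48 h, and the time of the DMSO libraries is not given. The groups were labelled DMSO (the solvent), HPA-12 (an inhibitor of the ceramide transfer protein CERT), crenolanib (a FLT3 kinase inhibitor) and combination. Doses are not given in the sources used here, and the labels do not say whether the libraries of a group came from separate cultures. P-values therefore measure only the spread between these libraries. Means are given in FPKM with the SD of 3 libraries, and changes as log2 fold changes with their standard error.

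Estimated depth was 14.5 ± 1.33 M reads in the DMSO libraries (13.6 to 15.99), 12.4 ± 0.364 M with HPA-12 (12.1 to 12.8), 10.1 ± 0.0894 M with crenolanib (10.1 to 10.2) and 4.69 ± 0.344 M with the combination (4.40 to 5.07). The 13 mitochondrially encoded genes held 19.8 ± 0.209% of the FPKM sum in DMSO, 21.6 ± 0.472% with HPA-12, 36.0 ± 0.119% with crenolanib and 62.2 ± 0.502% with the combination. Of the genes in the table, a mean of 5183 were listed at 0 in DMSO, 4836 with HPA-12, 4948 with crenolanib and 7971 with the combination. Across genes, which are not independent replicates, libraries of a group correlated at 0.996 to 0.997 in DMSO, 0.993 to 0.996 with HPA-12, 0.984 with crenolanib and 0.907 to 0.909 with the combination. The first principal component held 56.4% of the variance and set the combination libraries apart from the rest. Values of the combination libraries are thus the least precise.

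**Figure D1:**
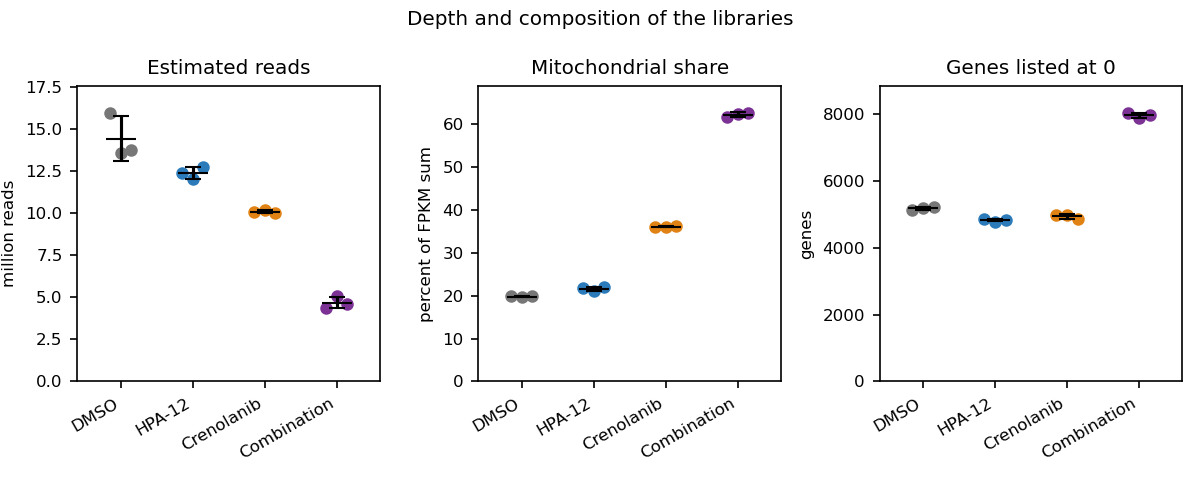
Points show each library by group for estimated reads (M), the percent of the FPKM sum in mitochondrially encoded genes, and the number of genes listed at 0, with bars for the mean and SD of 3 libraries. The combination libraries had the fewest reads (4.69 M), the highest mitochondrial share (62.2%) and the most genes at 0 (7971).

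HPA-12 vs DMSO asked what the CERT inhibitor did alone. In the libraries labelled HPA-12, MYC, a transcription factor that drives growth, went from 158 ± 2.43 to 6.88 ± 0.232 FPKM (-4.33 ± 0.08, adjusted p = 3.9e-12), and myeloperoxidase (MPO), an enzyme of neutrophil granules, from 391 ± 1.57 to 15.9 ± 0.663 FPKM (-4.53 ± 0.04, adjusted p = 2.0e-14). The chaperones FKBP4 (-3.58 ± 0.15), HSPA8 (-2.88 ± 0.05) and HSP90AB1 (-2.50 ± 0.04) fell, as did SRM, which makes spermidine (-3.54 ± 0.17), and PYCR1, which makes proline (-3.30 ± 0.22). The neutrophil-attracting chemokine CXCL8 rose by 4.52 ± 0.10, the growth factor BMP6 by 3.84 ± 0.35 and the immune receptor PDCD1 by 3.62 ± 0.10. Of 11149 genes tested, 5652 changed, 3088 up and 2564 down, and 1878 of them by more than 1 log2 unit.

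Among the genes named in the series title and their partners, HSPA5 (GRP78, ENSG00000044574), the main chaperone of the endoplasmic reticulum, fell from 82.3 ± 4.64 to 26.8 ± 0.502 FPKM (-1.58 ± 0.07, adjusted p = 7.1e-09). XBP1 (ENSG00000100219), a transcription factor of the unfolded protein response, fell by 1.35 ± 0.17. ATF4 (ENSG00000128272), the transcription factor of the integrated stress response, rose by 0.87 ± 0.09, FLT3 (ENSG00000122025) by 0.71 ± 0.05 and CERT1 (ENSG00000113163), the gene of the inhibitor's target, by 0.65 ± 0.17. DDIT3 (CHOP, ENSG00000175197) had 2.25 ± 0.656 FPKM in DMSO and 2.68 ± 0.5 with HPA-12 (0.19 ± 0.45, adjusted p = 0.756). ATF6 (ENSG00000118217) had 4.34 ± 0.171 and 6.24 ± 0.37 FPKM (0.44 ± 0.26, adjusted p = 0.19), and the same difference passed in a fit without the combination libraries (adjusted p = 0.00032).

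Genes of several fixed lists fell together in the libraries labelled HPA-12. Of 25 tested MYC targets and ribosome biogenesis genes, 24 fell and 1 rose (median -1.88, camera adjusted p = 5.6e-16), among them MRTO4 (-2.79 ± 0.10) and BOP1 (-2.54 ± 0.08), both needed to build ribosomes. Of 16 cytosolic heat shock genes, 15 fell, or 16 adjusted over the list alone (median -1.06, adjusted p = 1.4e-10), with HSPD1 at -2.42 ± 0.09 and HSPH1 at -1.85 ± 0.08. Of 20 ATF6-branch chaperone and degradation genes, 12 fell and 2 rose (median -0.65, adjusted p = 0.00169), and the chaperones CALR (-1.87 ± 0.08), PDIA4 (-1.48 ± 0.14) and HYOU1 (-1.02 ± 0.09) fell with HSPA5. Among 14 MAPK output genes, 9 fell, or 10 adjusted over the list alone, and 3 rose (median -1.17, adjusted p = 0.00744, and adjusted p = 0.204 over genes with a mean of at least 5 FPKM), with the phosphatase DUSP4 at -3.10 ± 0.13 and the early gene FOS at 2.95 ± 0.06. Of 15 FLT3-STAT5 output genes, 10 fell and 2 rose (median -0.68, adjusted p = 0.00329), with the kinase PIM1 at -1.90 ± 0.10 and DUSP6 at -1.57 ± 0.14.

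Further lists that fell hold genes of the proteasome, of energy metabolism and of DNA replication. Of 24 proteasome genes, 18 fell and 1 rose (median -0.66, adjusted p = 1.2e-06), with PSMA7 at -1.14 ± 0.06. Of 27 nuclear-encoded oxidative phosphorylation genes, 18 fell and 0 rose (1 adjusted over the list alone; median -0.54, adjusted p = 1.0e-05), with cytochrome c (CYCS) at -1.52 ± 0.11. Of 28 DNA replication genes, 14 fell and 1 rose (median -0.59, adjusted p = 0.0013), with CDC25A at -1.64 ± 0.19, while CDT1 rose by 0.67 ± 0.10. Of 21 glycolysis and hypoxia genes, 12 fell and 5 rose (median -0.60, adjusted p = 0.00392, and adjusted p = 0.132 with an estimated correlation), with enolase (ENO1) at -1.86 ± 0.05.

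Lists that rose with HPA-12 were led by replication-dependent histones, of which 10 of 12 rose, or 11 adjusted over the list alone (median 2.32, adjusted p = 1.2e-06), with H2AC6 at 3.63 ± 0.15. Histone genes have near-identical copies, so values of single ones are uncertain. Of 22 interferon-stimulated genes, 16 rose, or 20 adjusted over the list alone, and 2 fell (median 1.01, adjusted p = 2.8e-05, and adjusted p = 0.255 over genes with a mean of at least 5 FPKM), with IFIT2 at 2.16 ± 0.18 and STAT2 at 1.91 ± 0.07. Of 28 autophagy and lysosome genes, 18 rose, or 19 adjusted over the list alone, and 2 fell (median 0.52, adjusted p = 0.00013), with cathepsin B (CTSB) at 1.87 ± 0.08 and GABARAPL1 at 1.81 ± 0.14. In the KMT2A-fusion programme 9 of 15 genes rose and 1 fell (median 0.47, adjusted p = 0.0152, and adjusted p = 0.132 with an estimated correlation), with JMJD1C at 1.34 ± 0.13. Of 26 ribosomal protein and elongation factor genes, 15 rose and 2 fell (median 0.13, adjusted p = 0.0334, and adjusted p = 0.455 with an estimated correlation), and this call ended under median-ratio scaling (adjusted p = 0.082).

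The other lists did not pass as deposited. Sphingolipid and ceramide transport genes, the pathway of the inhibitor's target, had 4 of 30 raised and 3 lowered (median 0.02, mean -0.01, adjusted p = 0.995). Of 29 PERK-ATF4-CHOP genes 6 rose and 9 fell (adjusted p = 0.441), and of 21 IRE1-XBP1 genes 1 rose and 6 fell (adjusted p = 0.265). Cholesterol genes had 7 of 23 raised and 6 lowered, or 7 adjusted over the list alone (median 0.09, mean -0.06, adjusted p = 0.844). Fatty acid genes had 5 of 14 raised and 6 lowered, or 6 and 7 adjusted over the list alone (adjusted p = 0.196). LXR targets had 3 of 7 raised (adjusted p = 0.123). The BCL2 family had 5 of 14 raised and 5 lowered, or 6 adjusted over the list alone (median -0.01, mean 0.19, adjusted p = 0.833). The p53 targets had 8 of 18 raised and 2 lowered, or 9 and 3 adjusted over the list alone (adjusted p = 0.132). Monocyte genes had 4 of 21 raised and 7 lowered, or 8 adjusted over the list alone (adjusted p = 0.491). NF-kB genes had 10 of 18 raised, or 11 adjusted over the list alone, and 5 lowered (adjusted p = 0.0749). NRF2 genes had 3 of 14 raised and 7 lowered, or 8 adjusted over the list alone (adjusted p = 0.0731). Mitosis genes had 8 of 25 raised, or 7 adjusted over the list alone (adjusted p = 0.0821), erythroid and megakaryocytic markers 3 of 11 raised (adjusted p = 0.0749), and mitochondrially encoded genes 4 of 13 raised and 4 lowered (adjusted p = 0.987). With genes above 0 in all 12 libraries, NF-kB genes (0.51, adjusted p = 0.0133) and erythroid markers (0.61, adjusted p = 0.0296) passed.

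Over all genes tested, 79.5% had HPA-12 libraries wholly above or wholly below DMSO in 3 of 3 libraries, where chance gives 10%. The median change of all genes was 0.09 as deposited and 0.17 with mitochondrial genes left out of the total, and a fit of these 2 groups alone called 8672 genes.

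**Figure D2:**
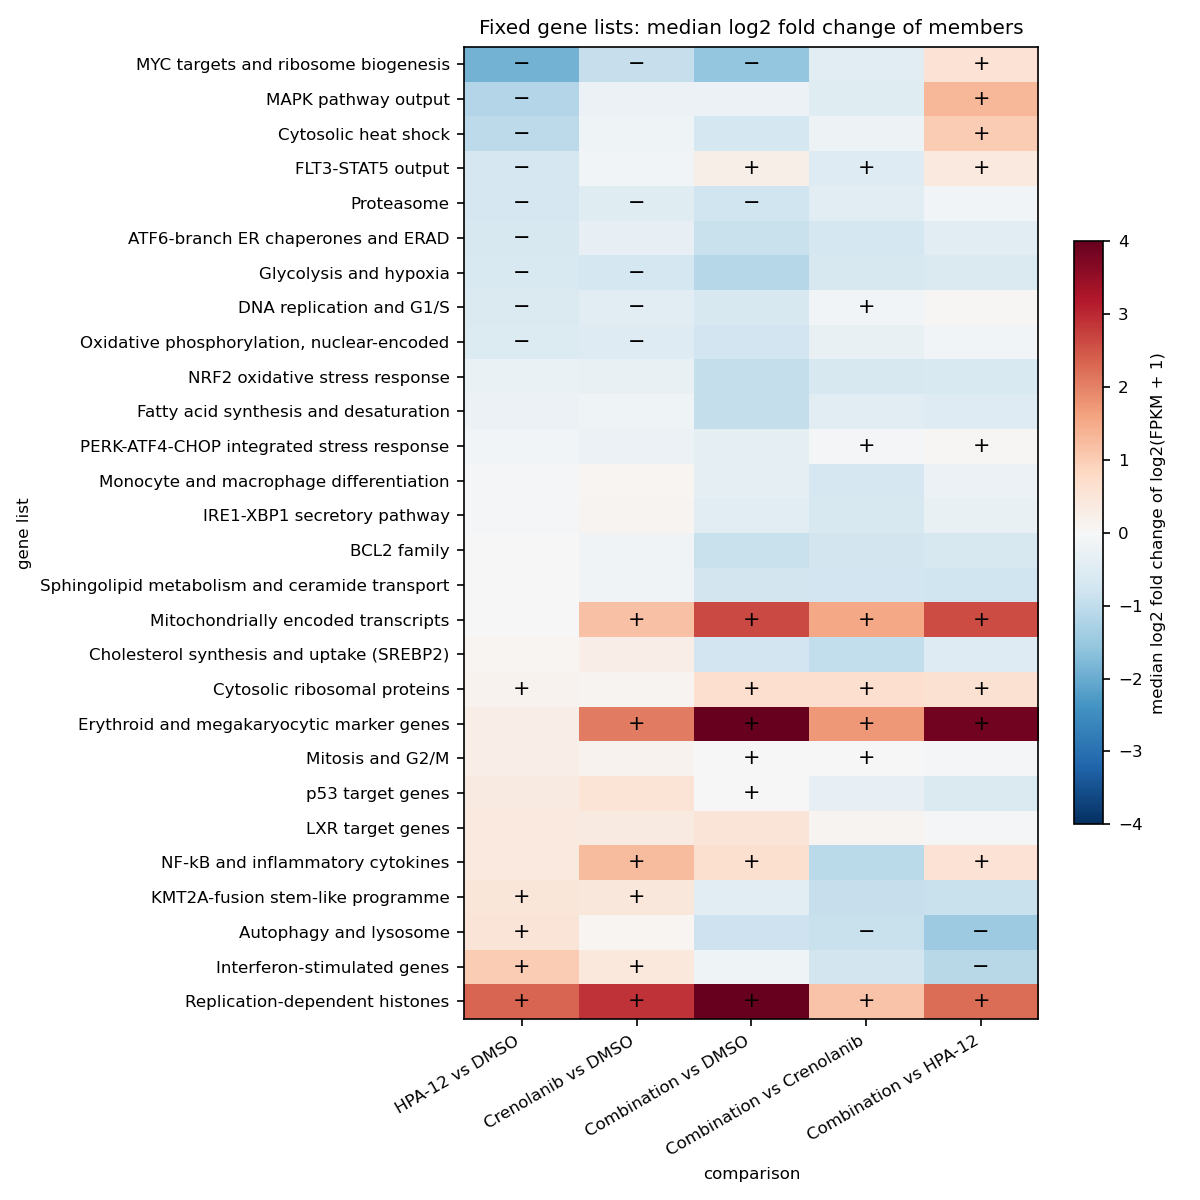
Colour shows the median log2 fold change of the tested members of 28 fixed lists (vertical axis) in 5 comparisons (horizontal axis), and + or - marks an adjusted camera p under 0.05 with the direction relative to all other genes. Mitochondrially encoded, erythroid and histone genes were the most raised with the combination, whose colours include the shift of all genes (median -0.62 against DMSO), so that FLT3-STAT5 genes are blue but marked + against crenolanib; medians of that list and of PERK-ATF4-CHOP, DNA replication and mitosis genes turn positive there under median-ratio scaling.

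Crenolanib vs DMSO asked what the FLT3 inhibitor did alone. In the libraries labelled crenolanib, ARC rose from 0.0313 ± 0.0149 to 713 ± 12.1 FPKM (9.44 ± 0.08, adjusted p = 1.5e-15) and EGR1, a transcription factor induced by growth signals, from 2.52 ± 0.22 to 255 ± 15.5 FPKM (6.19 ± 0.10). The small GTPases RASD1 (7.80 ± 0.09) and RRAD (6.44 ± 0.17), the chemokines CXCL8 (7.76 ± 0.10) and CXCL2 (6.05 ± 0.16), the survival gene BCL2A1 (6.10 ± 0.25) and C12orf57 (5.88 ± 0.12) rose too. The most lowered genes changed less, with MYC at -2.15 ± 0.08 (34.8 ± 3.29 FPKM), SIGLEC12 at -2.08 ± 0.33, the tRNA methylation gene WDR4 at -2.02 ± 0.31 and MYBBP1A at -1.98 ± 0.21. HBB, the beta-globin gene of red cells, rose from 70.0 ± 4.06 to 4026 ± 136 FPKM (5.83 ± 0.04, adjusted p = 5.8e-16). In all, 6274 genes changed, 3054 up and 3220 down, and 2053 by more than 1 log2 unit.

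HSPA5 fell to 62.3 ± 1.24 FPKM (-0.39 ± 0.07, adjusted p = 0.000436) and XBP1 by 0.93 ± 0.17. ATF4 rose by 0.68 ± 0.09, FLT3 by 0.46 ± 0.05 and CERT1 by 1.09 ± 0.17, from 1.60 ± 0.0476 to 4.54 ± 0.199 FPKM. DDIT3 had 3.29 ± 2.79 FPKM (0.22 ± 0.45, adjusted p = 0.695), a spread close to its mean. ATF6 had 6.55 ± 0.432 FPKM (0.50 ± 0.26, adjusted p = 0.129), and this difference passed in the fit without the combination libraries (adjusted p = 9.7e-05).

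All 13 mitochondrially encoded genes rose with crenolanib (median 1.16, camera adjusted p = 2.2e-11), with MT-CYB at 1.26 ± 0.04 and MT-ND5 at 0.95 ± 0.03. Beside them, 9 of 11 erythroid and megakaryocytic markers rose and 0 fell (median 2.09, adjusted p = 8.8e-06), among them the haem synthesis gene ALAS2 (4.14 ± 0.09) and the membrane gene GYPB (2.80 ± 0.21). Of 12 histone genes 11 rose (median 2.90, adjusted p = 6.9e-08), with H1-4 at 5.47 ± 0.20 and H4C3 at 4.66 ± 0.14. Of 18 NF-kB and cytokine genes 12 rose and 5 fell (median 1.26, adjusted p = 0.000217), with NFKB1 at 2.87 ± 0.08 and its inhibitor NFKBIA at 2.26 ± 0.06. Of 22 interferon-stimulated genes 11 rose and 2 fell (median 0.41, adjusted p = 0.0257, and adjusted p = 0.0734 with an estimated correlation), with IFIT2 at 1.85 ± 0.18. Over genes with a mean of at least 5 FPKM the median of this list was -0.14 (adjusted p = 0.771). In the KMT2A-fusion programme 9 of 15 genes rose (median 0.46, adjusted p = 0.0134, and adjusted p = 0.128 with an estimated correlation), with JMJD1C at 2.16 ± 0.13 and the kinase CDK6 at 0.89 ± 0.12.

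Of the MYC targets 21 fell, or 22 adjusted over the list alone, and 1 rose (median -0.93, adjusted p = 8.4e-07), with the pyrimidine synthesis gene CAD at -1.71 ± 0.10 and the NAD synthesis gene NAMPT at 3.10 ± 0.10. Oxidative phosphorylation genes had 16 of 27 lowered and 1 raised (median -0.51, adjusted p = 0.00122), with UQCRC1 at -1.29 ± 0.08. Proteasome genes had 16 of 24 lowered and 3 raised (median -0.49, adjusted p = 0.00731), with PSMB3 at -1.29 ± 0.12. DNA replication genes had 15 of 28 lowered and 0 raised (median -0.43, adjusted p = 0.0071, and adjusted p = 0.0931 with an estimated correlation), with the helicase gene MCM2 at -1.47 ± 0.18. Glycolysis genes had 12 of 21 lowered, or 13 adjusted over the list alone, and 6 raised (median -0.70, adjusted p = 0.036, and adjusted p = 0.275 with an estimated correlation), with GAPDH at -0.94 ± 0.05.

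Neither list of signalling output passed with crenolanib. MAPK output had 6 of 14 members raised and 7 lowered (median -0.22, mean 0.92, adjusted p = 0.484), and FLT3-STAT5 output 7 of 15 raised and 5 lowered (median -0.10, mean 0.69, adjusted p = 0.188). Both means were positive with negative medians. ATF6-branch genes had 5 of 20 raised and 10 lowered (adjusted p = 0.136), and PERK-ATF4-CHOP genes 8 of 29 raised and 10 lowered (median -0.24, mean 0.17, adjusted p = 0.885). Sphingolipid genes had 9 of 30 raised and 8 lowered, or 9 adjusted over the list alone (adjusted p = 0.885). NRF2 genes also differed in sign between the median (-0.29) and the mean (0.13), with an adjusted p of 0.595.

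Over all genes tested, 77.8% had crenolanib libraries wholly above or wholly below DMSO in 3 of 3 libraries (10% by chance). The median change of all genes was -0.04, and 48.7% of the changed genes had risen, against 58.6% under upper-quartile scaling.

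Responses to the single agents resembled each other. Over 11149 genes, which are not independent replicates, the fold changes with HPA-12 and with crenolanib correlated at r = 0.68 (rho 0.72). Both use the same 3 DMSO libraries, and simulations with no true change gave r = 0.29 and a covariance of 0.0035, against 0.476 measured, a difference of 0.472. Both treatments raised 1889 genes (846 if the calls were independent) and lowered 1908 (741 if independent). The 3 DMSO libraries could not be split between the comparisons with 2 in each, so part of this excess in counts may come from them. Another 154 rose with HPA-12 and fell with crenolanib and 94 did the reverse. Among MAPK and FLT3-STAT5 output genes, 18 of 28 were lower in the libraries labelled HPA-12 than in those labelled crenolanib, and 0 were higher. Of these 18, 11 had also fallen with HPA-12 against DMSO. SOCS1, a feedback inhibitor induced by STAT5, had 4.62 ± 0.427 FPKM in DMSO, 1.93 ± 0.311 with HPA-12 and 164 ± 7.97 with crenolanib.

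**Figure D3:**
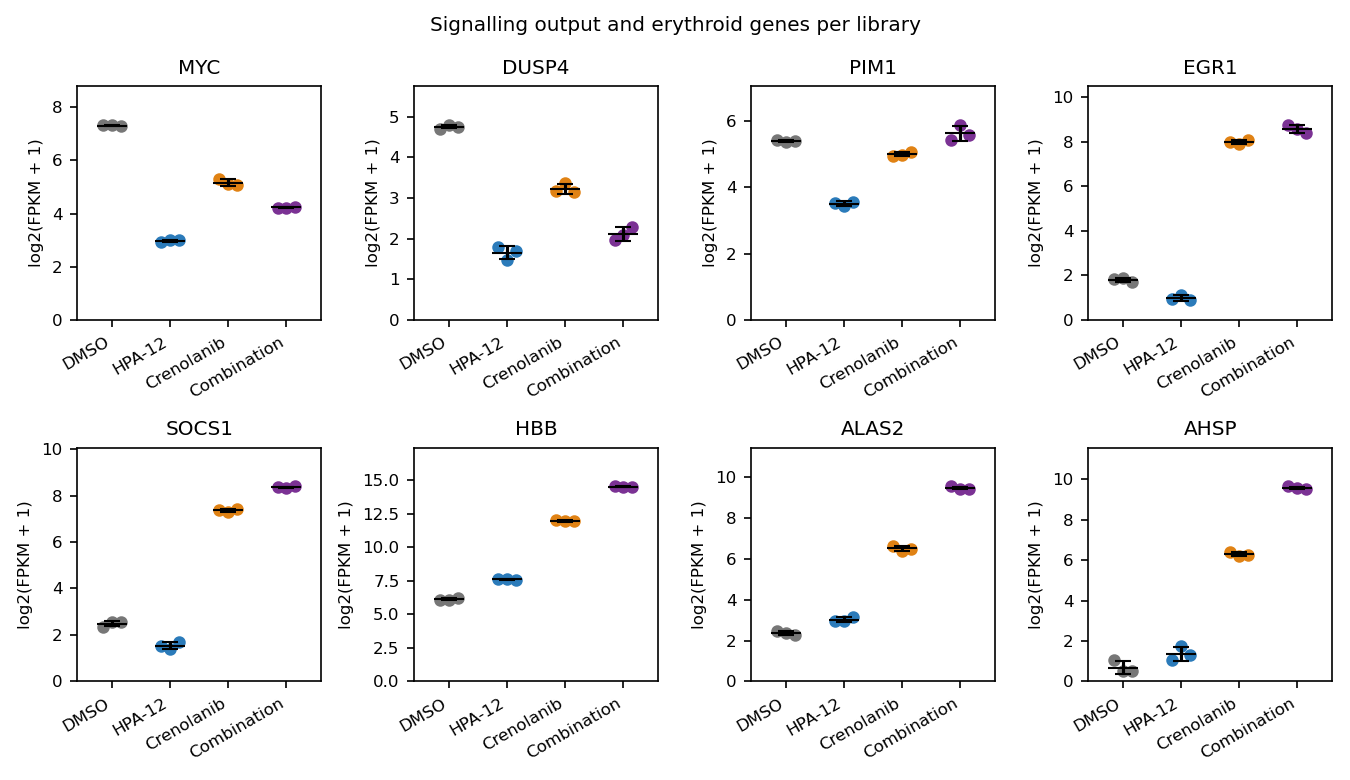
Points show log2(FPKM + 1) of 8 genes in each library by group, with bars for the mean and SD of 3 libraries. MYC, DUSP4 and PIM1 were lowest in the libraries labelled HPA-12 among the single agents, EGR1 and SOCS1 rose only with crenolanib and the combination in these 4 groups, and HBB, ALAS2 and AHSP rose stepwise from DMSO to the combination.

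Combination vs DMSO asked what both compounds did together. The largest rises were those of ARC (10.14 ± 0.08, to 1167 ± 81.6 FPKM), RASD1 (8.98 ± 0.09) and GADD45G, a stress gene (7.56 ± 0.13), and of red cell genes. HBB reached 23848 ± 58.6 FPKM (8.39 ± 0.04, adjusted p = 8.7e-18). The other globin HBM (8.99 ± 0.16), the globin chaperone AHSP (8.90 ± 0.18), carbonic anhydrase CA1 (8.29 ± 0.07) and HEMGN (8.07 ± 0.16) rose with it. Most lowered were SIGLEC12 (-3.999 ± 0.33), NTSR1 (-3.43 ± 0.34), TRIP6 (-3.41 ± 0.15), thrombomodulin (THBD, -3.19 ± 0.15), LENG1 (-3.15 ± 0.31), the ribosome assembly gene RRS1 (-3.11 ± 0.37), MRPL58 (-3.11 ± 0.64) and P2RY2 (-3.10 ± 0.18).

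HSPA5 fell by 0.32 ± 0.07 as deposited, and rose by 0.36 under median-ratio and 0.47 under upper-quartile scaling. XBP1 fell by 0.95 ± 0.17, which did not pass under those scalings (-0.27 and -0.16). ATF4 rose by 0.64 ± 0.09 to 138 ± 21.4 FPKM. FLT3 fell by 0.69 ± 0.05 to 58.4 ± 3.12 FPKM, against 0.00 and 0.11, neither of which passed, under the same 2 scalings. DDIT3 had 3.68 ± 2.88 FPKM (0.37 ± 0.45, adjusted p = 0.475). ATF6 had 3.45 ± 2.17 FPKM (-0.38 ± 0.26, adjusted p = 0.219), and without combination library 2 the difference passed at -0.74 (adjusted p = 0.0022). Without combination library 3 it was -0.03 (adjusted p = 0.894). CERT1 rose by 0.43 ± 0.17 (adjusted p = 0.0366) with overlapping groups, a call lost without combination library 1 (0.36, adjusted p = 0.087) or 2 (0.30, adjusted p = 0.11), and without DMSO library 1, 2 or 3 (adjusted p of 0.084, 0.071 and 0.086).

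**Figure D4:**
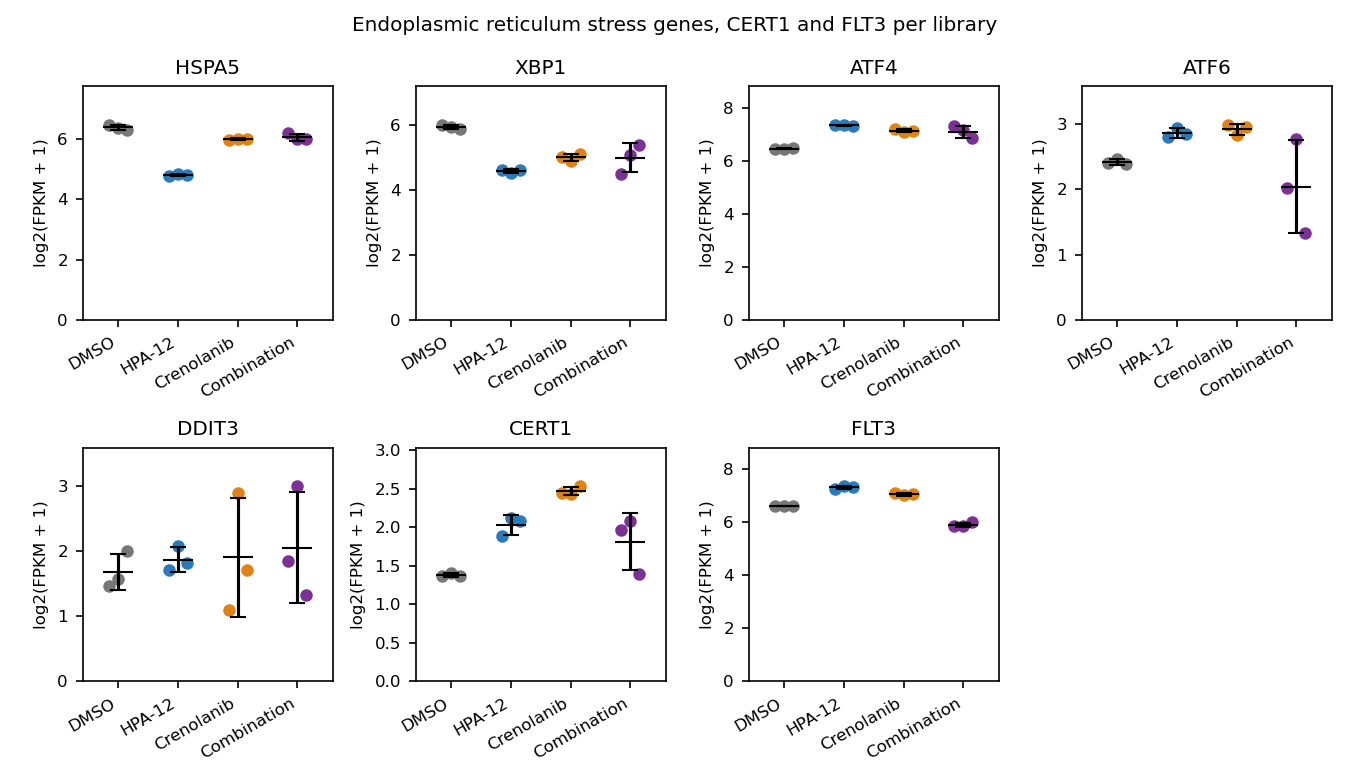
Points show log2(FPKM + 1) of 7 genes in each library by group, with bars for the mean and SD of 3 libraries. HSPA5 and XBP1 were lowest with HPA-12, while ATF6, DDIT3 and CERT1 were spread widely in the combination libraries; the change of HSPA5 with the combination against DMSO turns from -0.32 to 0.36 under median-ratio scaling.

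All 13 mitochondrially encoded genes rose (median 2.64, adjusted p = 1.7e-21), MT-CO1 to 60887 ± 434 FPKM (2.01 ± 0.03). Ribosomal protein and elongation factor genes had 25 of 26 raised (median 0.66, adjusted p = 1.7e-20), with RPS12 at 1.93 ± 0.08 and RPS6 at 1.61 ± 0.04, while the elongation factor EEF2 fell by 1.24 ± 0.04. All 12 histone genes rose (median 3.97, adjusted p = 4.1e-13), with H1-2 at 5.79 ± 0.14. Erythroid and megakaryocytic markers had 10 of 11 raised (median 4.10, adjusted p = 3.9e-12), with ALAS2 at 7.10 ± 0.09. Of 2 megakaryocytic genes named after their values were seen, ITGA2B rose less (1.08, adjusted p = 0.00144) and GP1BA did not pass (-0.66, adjusted p = 0.192). NF-kB genes had 10 of 18 raised and 7 lowered (median 0.64, adjusted p = 0.00056), with CXCL8 at 6.23 ± 0.10 and the interleukin antagonist IL1RN at -3.00 ± 0.13. FLT3-STAT5 output had 7 of 15 raised, or 8 adjusted over the list alone, and 6 lowered (median 0.23, adjusted p = 0.00326), with SOCS1 at 5.86 ± 0.09 and LCN2 at 5.16 ± 0.15.

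MYC targets had 23 of 25 lowered and 2 raised (median -1.55, adjusted p = 0.00624, and adjusted p = 0.0554 with an estimated correlation), with MYC at -3.08 ± 0.08 and the transferrin receptor TFRC at 1.83 ± 0.07. Mitosis genes had 11 of 25 raised and 8 lowered (median 0.01, adjusted p = 0.00485, and adjusted p = 0.0695 with an estimated correlation), with DLGAP5 at 1.80 ± 0.12 and PLK1 at -1.50 ± 0.14. The p53 targets had 6 of 18 raised and 6 lowered (median 0.02, adjusted p = 0.0335, and adjusted p = 0.0695 with an estimated correlation), with the cell cycle inhibitor CDKN1A at 3.54 ± 0.10, the death gene BBC3 at 2.17 ± 0.18 and BAX at -1.08 ± 0.08; this call ended without combination library 2 (median -0.06, adjusted p = 0.067). Proteasome genes had 20 of 24 lowered and 1 raised (median -0.79, adjusted p = 0.0335, and adjusted p = 0.0695 with an estimated correlation), with PSMD3 at -2.01 ± 0.12, and this call ended under median-ratio scaling (median -0.15, adjusted p = 0.62) and without combination library 2 (adjusted p = 0.054). ATF6-branch genes had 16 of 20 lowered and 1 raised without passing against other genes (median -0.88, adjusted p = 0.081). PERK-ATF4-CHOP genes had 7 of 29 raised and 12 lowered (median -0.35, mean 0.04, adjusted p = 0.192), and sphingolipid genes 3 of 30 raised and 20 lowered, or 21 adjusted over the list alone (adjusted p = 0.43).

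Of the genes tested, 7951 changed, 1652 up and 6299 down, with a median over all genes of -0.62. Under median-ratio scaling the median was -0.12, and 6809 genes changed, 3036 up and 3773 down. The share that had risen was 20.8% as deposited, 44.6% under median-ratio and 49.2% under upper-quartile scaling, so changes of a single gene near these medians depend on the scaling. Combination libraries were wholly above or below DMSO in 3 of 3 libraries for 71.4% of all genes tested (10% by chance). Simulated libraries with these spreads gave 276 false calls in this comparison, with few genes changed. That number does not measure the false calls among the 7951.

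Combination vs crenolanib asked what HPA-12 added to crenolanib, the sensitisation of the series title. Among the genes that stood highest in the libraries labelled combination above those labelled crenolanib were several red cell genes. They were HBM (3.46 ± 0.16), AHSP (3.29 ± 0.18), CA1 (3.13 ± 0.07) and the membrane protein genes EPB42 (3.12 ± 0.12) and KEL (3.12 ± 0.12). MYL4 (3.34 ± 0.19) and OSBP2 (3.06 ± 0.10) ranked with them. HBB rose by 2.57 ± 0.04. Most lowered were the fatty acid binding gene FABP3 (-2.64 ± 0.35), NRBF2 (-2.56 ± 0.45), MARCKS (-2.50 ± 0.11), IQCN (-2.49 ± 0.26), PRUNE1 (-2.46 ± 0.59), the channel AQP9 (-2.39 ± 0.40), TCFL5 (-2.38 ± 0.14) and the haem-degrading enzyme HMOX1 (-2.37 ± 0.10).

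None of HSPA5, XBP1, ATF4 and DDIT3 passed in this comparison as deposited. HSPA5 had 65.7 ± 5.17 FPKM against 62.3 ± 1.24 (0.07 ± 0.07, adjusted p = 0.362), and 0.75 under median-ratio and 0.71 under upper-quartile scaling, where it passed. ATF4 (-0.04 ± 0.09, adjusted p = 0.686) rose under those scalings (0.64 and 0.60), and so did XBP1 (-0.02 ± 0.17, adjusted p = 0.918, against 0.65 and 0.60). DDIT3 was at 0.15 ± 0.45 (adjusted p = 0.776). ATF6 fell by 0.88 ± 0.26 (adjusted p = 0.0114) and CERT1 by 0.65 ± 0.17 (adjusted p = 0.00463) as deposited, and neither passed under median-ratio scaling (-0.34 and -0.13). ATF6 was at -0.53 without combination library 3 and at -1.24 without library 2, and passed in both. These fits also use 1 spread per gene for all groups. ATF6 had 3.03, 5.79 and 1.52 FPKM in the combination libraries, against 6.88, 6.06 and 6.70 with crenolanib. Its standard error thus understates the spread of the combination libraries. The same holds for CERT1 (2.89, 3.24 and 1.63 FPKM with the combination, 4.44, 4.40 and 4.76 with crenolanib). FLT3 fell by 1.14 ± 0.05, and by 0.47 under median-ratio scaling.

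Ribosomal protein and elongation factor genes had 24 of 26 raised and 1 lowered (median 0.68, adjusted p = 6.5e-33), with RPSA at 1.09 ± 0.06 and RPS6 at 0.89 ± 0.04. All 13 mitochondrially encoded genes rose (median 1.56, adjusted p = 2.8e-29), with MT-CO2 at 1.72 ± 0.04. Erythroid and megakaryocytic markers had 9 of 11 raised (median 1.73, adjusted p = 7.1e-14), with ALAS2 at 2.96 ± 0.09. The megakaryocytic genes GP1BA (-0.77, adjusted p = 0.132) and ITGA2B (0.19, adjusted p = 0.476), named after their values were seen, did not pass. Histones had 8 of 12 raised and 3 lowered (median 1.13, adjusted p = 3.8e-06), with H1-2 at 2.08 ± 0.14 and H2AC6 at -1.27 ± 0.15. Autophagy and lysosome genes had 23 of 28 lowered and 1 raised (median -0.90, adjusted p = 0.0137, and adjusted p = 0.0601 with an estimated correlation), with progranulin (GRN) at -1.65 ± 0.05, and this call ended under median-ratio scaling (-0.29, adjusted p = 0.15). ATF6-branch genes had 14 of 20 lowered and 0 raised without passing against other genes (median -0.69, adjusted p = 0.527), and sphingolipid genes 21 of 30 lowered and 1 raised (adjusted p = 0.527). Oxidative phosphorylation and heat shock genes did not pass as deposited (medians -0.30 and -0.19) but passed under median-ratio (0.33 and 0.36) and upper-quartile scaling (0.30 and 0.32).

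Among 4 lists the test pointed up while the median was negative as deposited and positive under median-ratio scaling. FLT3-STAT5 output had 7 of 15 raised and 8 lowered (median -0.51, mean 0.08, adjusted p = 0.00715, and adjusted p = 0.0601 with an estimated correlation; 0.17 under that scaling), with LCN2 at 1.85 ± 0.15 and the survival gene MCL1 at -0.88 ± 0.05. Mitosis genes had 5 of 25 raised and 8 lowered (median -0.01, adjusted p = 0.00327, and adjusted p = 0.0645 with an estimated correlation; 0.63 under that scaling). PERK-ATF4-CHOP genes had 6 of 29 raised and 12 lowered (median -0.08, mean -0.13, adjusted p = 0.0242, and adjusted p = 0.0627 with an estimated correlation; 0.52 under that scaling), with DDIT4 at 0.90 ± 0.07 and the cystine transporter SLC7A11 at -1.97 ± 0.14. DNA replication genes had 4 of 28 raised and 12 lowered, or 11 adjusted over the list alone (median -0.12, adjusted p = 0.0431, and adjusted p = 0.186 with an estimated correlation; 0.42 under that scaling), with RRM2 at 1.26 ± 0.14 and MCM4 at -0.93 ± 0.10. The last call ended without combination library 3 (median -0.28, adjusted p = 0.12) or crenolanib library 3 (adjusted p = 0.054), and that of PERK-ATF4-CHOP genes without combination library 1 (median -0.23, adjusted p = 0.05).

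In all 7803 genes changed, 979 up and 6824 down, with a median over all genes of -0.63 as deposited. Median-ratio scaling gave -0.13 and 5112 genes, 2185 up and 2927 down. Combination libraries were wholly above or below crenolanib in 3 of 3 libraries for 64.9% of all genes tested (10% by chance). Simulated libraries gave 393 false calls, with few genes changed. That number does not measure the false calls among the 7803.

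Combination vs HPA-12 asked what crenolanib added to HPA-12. ARC (9.91 ± 0.08), RASD1 (8.36 ± 0.09), AHSP (8.21 ± 0.18), HBM (7.99 ± 0.16) and EGR1 (7.60 ± 0.10) rose the most over the libraries labelled HPA-12. The ligand CD70 (-3.77 ± 0.30), TMEM86A (-3.66 ± 0.34), the death gene BMF (-3.53 ± 0.15), GIPR (-3.48 ± 0.12) and the cytokine receptor CRLF2 (-3.45 ± 0.21) fell the most. HSPA5 rose by 1.26 ± 0.07, FLT3 fell by 1.40 ± 0.05 and ATF6 fell by 0.82 ± 0.26, the last without passing under median-ratio scaling (-0.24, adjusted p = 0.48). ATF6 was at -0.47 without combination library 3 and at -1.18 without library 2, and passed in both. Here too its standard error understates the spread of the combination libraries. XBP1 rose by 0.40 ± 0.17 (adjusted p = 0.0472) with overlapping groups, a call lost without combination library 3 (0.21, adjusted p = 0.19) or 2 (0.36, adjusted p = 0.11) and without HPA-12 library 1, 2 or 3 (adjusted p of 0.081, 0.12 and 0.08). ATF4 fell by 0.24 ± 0.09 (adjusted p = 0.032) as deposited and rose by 0.48 under median-ratio scaling, with the call lost without HPA-12 library 1, 2 or 3 (adjusted p of 0.075, 0.067 and 0.064) or combination library 3 (-0.11, adjusted p = 0.088). CERT1 (-0.22 ± 0.17, adjusted p = 0.265) and DDIT3 (0.18 ± 0.45, adjusted p = 0.729) did not pass.

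Against HPA-12, MYC targets had 18 of 25 raised and 3 lowered (median 0.58, adjusted p = 2.2e-09), with TFRC at 3.65 ± 0.07 and MYC itself at 1.25 ± 0.08. Heat shock genes had 12 of 16 raised and 1 lowered (median 1.00, adjusted p = 1.0e-10), with HSPA8 at 1.08 ± 0.05; HSPA1A and HSPA1B rose as well but are near-identical copies. MAPK output had 9 of 14 raised and 1 lowered (median 1.33, adjusted p = 1.4e-07), with IER3 at 3.51 ± 0.08. FLT3-STAT5 output had 8 of 15 raised and 4 lowered (median 0.38, adjusted p = 1.6e-05), with ID1 at 5.60 ± 0.18. PERK-ATF4-CHOP genes had 11 of 29 raised and 12 lowered (median 0.06, adjusted p = 0.0112; -0.40 and 0.0697 over genes with a mean of at least 5 FPKM), with ATF3 at 3.54 ± 0.08 and GDF15 at 3.14 ± 0.17. NF-kB genes had 9 of 18 raised, or 10 adjusted over the list alone, and 6 lowered (median 0.58, adjusted p = 0.000679). Interferon-stimulated genes had 21 of 22 lowered (median -1.11, adjusted p = 0.013, and adjusted p = 0.335 over genes with a mean of at least 5 FPKM), with STAT2 at -2.96 ± 0.07. Autophagy genes had 25 of 28 lowered and 1 raised (median -1.46, adjusted p = 0.000568), with CTSB at -2.31 ± 0.08.

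Mitochondrially encoded genes (13 of 13 raised, median 2.60, adjusted p = 4.1e-22), ribosomal protein and elongation factor genes (25 of 26 raised, median 0.61, adjusted p = 2.1e-18), erythroid and megakaryocytic markers (9 of 11 raised and 1 lowered, median 3.87, adjusted p = 2.6e-11) and histones (8 of 12 raised and 4 lowered, median 2.24, adjusted p = 0.00016) stood apart here as well. Of 2 megakaryocytic genes named after their values were seen, GP1BA fell (-1.44, adjusted p = 0.0103) and ITGA2B did not pass (0.49, adjusted p = 0.079). The 12 list calls of this comparison held with an estimated correlation. Proteasome and mitosis genes did not pass as deposited (medians -0.11 and -0.05) but passed under median-ratio (0.54 and 0.61) and upper-quartile scaling (0.56 and 0.63). DNA replication and oxidative phosphorylation genes (medians 0.05 and -0.10 as deposited) also passed under median-ratio (0.59 and 0.28) and upper-quartile scaling (0.61 and 0.31). ATF6-branch genes passed under upper-quartile scaling (0.27, adjusted p = 0.0498). Mitosis genes also passed without combination library 1 (-0.07, adjusted p = 0.0461). In all 8064 genes changed, 1618 up and 6446 down (median over all genes -0.64), and 6770 under median-ratio scaling, 3062 up and 3708 down (median -0.11). Combination libraries were wholly above or below HPA-12 in 3 of 3 libraries for 70.7% of all genes tested (10% by chance). Simulated libraries gave 329 false calls, with few genes changed. That number does not measure the false calls among the 8064.

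The interaction asked whether the effect of HPA-12 on top of crenolanib differed from its effect on top of DMSO. MPO (4.85 ± 0.06), the amino acid transporter SLC38A5 (4.62 ± 0.19), DNPH1 (4.27 ± 0.45) and PYCR1 (4.15 ± 0.31) were among the genes with the most positive differences: HPA-12 alone lowered MPO to 15.9 ± 0.663 FPKM, while crenolanib alone left 344 ± 4.35 and the combination 429 ± 15.4. CXCL8 (-6.04 ± 0.14), PDCD1 (-5.87 ± 0.15), CRLF2 (-5.71 ± 0.30), IQCN (-5.31 ± 0.37) and MS4A14 (-5.29 ± 0.16) had the most negative: CXCL8 had 158 ± 24.5 FPKM with HPA-12, 1486 ± 32.8 with crenolanib and 517 ± 30.7 with the combination. HSPA5 (1.65 ± 0.10) and XBP1 (1.33 ± 0.24) had positive differences, and FLT3 (-1.85 ± 0.08) and CERT1 (-1.30 ± 0.24) negative ones. ATF4 (-0.92 ± 0.13) and ATF6 (-1.32 ± 0.37) had negative differences that did not pass under median-ratio scaling (-0.21 and -0.74). DDIT3 had none that passed (-0.04 ± 0.64, adjusted p = 0.962; 0.50 under median-ratio scaling, adjusted p = 0.54).

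Positive differences gathered in MYC targets (22 of 25 and 1 negative, median 1.71, adjusted p = 3.0e-16), with TFRC at 3.50 ± 0.10, and in heat shock genes (12 of 16, median 1.21, adjusted p = 1.1e-11), with HSPA8 at 2.45 ± 0.07. FLT3-STAT5 output (9 of 15 and 3 negative, median 1.27, adjusted p = 0.000242), MAPK output (10 of 14 and 3 negative, median 0.89, adjusted p = 0.000466), DNA replication (12 of 28 and 4 negative, median 0.46, adjusted p = 0.000242), oxidative phosphorylation (11 of 27 and 4 negative, or 3 adjusted over the list alone, median 0.25, adjusted p = 9.4e-05) and proteasome genes (9 of 24 and 4 negative, median 0.07, adjusted p = 0.00328) followed, the last with a median of -0.03 when mitochondrial genes were left out of the total. Mitochondrially encoded genes (13 of 13, median 1.34, adjusted p = 2.2e-16), ribosomal protein and elongation factor genes (23 of 26 and 2 negative, median 0.57, adjusted p = 2.9e-13) and erythroid and megakaryocytic markers (8 of 11, or 9 adjusted over the list alone, and 1 negative, median 1.37, adjusted p = 4.0e-06) were positive too. The megakaryocytic gene GP1BA, named after its values were seen, had a negative difference (-1.54, adjusted p = 0.0428). Negative differences gathered in autophagy genes (24 of 28 and 1 positive, median -1.41, adjusted p = 0.000241), interferon-stimulated genes (18 of 22, median -1.63, adjusted p = 0.00328, and adjusted p = 0.609 over genes with a mean of at least 5 FPKM) and the KMT2A-fusion programme (13 of 15, median -1.48, adjusted p = 0.00807, and adjusted p = 0.0951 with an estimated correlation), with SOX4 at -2.09 ± 0.11.

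Glycolysis genes (6 of 21 positive and 5 negative, or 4 and 5 adjusted over the list alone, median 0.14, adjusted p = 0.0129, and adjusted p = 0.194 with an estimated correlation) passed with members on both sides, TPI1 at 1.62 ± 0.09 and VEGFA at -2.10 ± 0.17. ATF6-branch genes (8 of 20 positive and 7 negative, median 0.08, mean -0.06, adjusted p = 0.0476, and adjusted p = 0.0878 with an estimated correlation) included CALR at 1.15 ± 0.12 and EDEM1 at -2.24 ± 0.16, and the call ended without combination library 3 (adjusted p = 0.1), DMSO library 1 (adjusted p = 0.056) or HPA-12 library 3 (adjusted p = 0.05). PERK-ATF4-CHOP genes did not pass as deposited (median -0.04) but passed under median-ratio (0.50, adjusted p = 0.025) and upper-quartile scaling (0.42, adjusted p = 0.0322). NF-kB genes (3 of 18 positive and 12 negative, median -1.74, adjusted p = 0.0904) passed under the same scalings (-1.08, adjusted p = 0.0287, and -1.20, adjusted p = 0.0347). They also passed with 3 other choices of genes. Of all genes 7293 had a difference that passed, 1720 positive and 5573 negative, with a median over all genes of -0.65. Under median-ratio scaling 6115 passed, 2831 positive and 3284 negative, with a median of -0.13.

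Markers of other cell types outside the erythroid list are given as values only. Of 12 lymphoid markers in the table, 3 had a mean of at least 1 FPKM in each of the 4 groups. Of 13 stromal and epithelial markers, 3 reached 1 FPKM with DMSO, HPA-12 and crenolanib, and 7 with the combination. In 4 of these 7 the SD exceeded the mean: COL1A1 (2.32 ± 3.89 FPKM), COL3A1 (2.91 ± 4.84), COL1A2 (1.25 ± 1.83) and LUM (1.12 ± 1.28). These 4 were named after their values were seen, as were the highest, NKG7 of the lymphoid list (60.9 ± 1.16 FPKM in DMSO, 47.1 ± 2.27 with HPA-12, 28.2 ± 5.86 with crenolanib and 21.6 ± 3.08 with the combination) and PECAM1 of the stromal and epithelial list (12.2 ± 0.438, 59.1 ± 1.77, 25.5 ± 1.95 and 6.34 ± 0.764 FPKM). The erythroid genes rose with the mitochondrial share: HBB had 70.0 ± 4.06 FPKM in DMSO, 197 ± 4.28 with HPA-12, 4026 ± 136 with crenolanib and 23848 ± 58.6 with the combination, and AHSP 0.635 ± 0.377, 1.64 ± 0.661, 77.2 ± 5.76 and 765 ± 32.5 FPKM in the same order. Values of HBA1 and HBA2, which have near-identical copies, are uncertain.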

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

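The tests of depth and of transcript length were planned, while the other tests in this part, including those on alpha-globin, on a shared erythroid source, on exchanged labels and on other splits of the libraries, were chosen after the results were seen.

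The effect of HPA-12 differed between crenolanib-treated and solvent-treated cells by the interaction term for 7293 genes and 15 gene lists. Of these genes 1720 were positive and 5573 negative, with a median over all genes of -0.65 as deposited. Under median-ratio scaling 6115 passed, 2831 positive and 3284 negative. The simulations of the gene test did not cover the interaction, which uses the same 1 spread per gene. Among the core genes the difference was 1.65 for HSPA5, 1.33 for XBP1, -0.92 for ATF4, -1.32 for ATF6, -1.30 for CERT1 and -1.85 for FLT3. Those of ATF4 (-0.21) and ATF6 (-0.74) did not pass under median-ratio scaling, and 3 of the 15 lists (ATF6-branch, KMT2A-fusion programme and glycolysis) did not pass with an estimated correlation. The other named genes were MPO (4.85), SLC38A5 (4.62), DNPH1 (4.27), PYCR1 (4.15), CXCL8 (-6.04), PDCD1 (-5.87), CRLF2 (-5.71), IQCN (-5.31) and MS4A14 (-5.29). Of 100 splits of the 12 libraries drawn at random, 1 gave as many genes, the real one, and the highest of the others gave 2144. These splits mix libraries of groups that differ strongly, so they test whether the groups differ at all. They cannot decide whether the interaction itself exceeds chance. Each pairwise comparison has only 10 splits, too few for a share under 0.05. In each of them 1 split, the real one, gave as many genes (5652 for HPA-12 vs DMSO, 6274 for crenolanib vs DMSO, 7951 for combination vs DMSO, 7803 for combination vs crenolanib and 8064 for combination vs HPA-12), and the highest of the others gave 0.

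Erythroid transcripts rose in the crenolanib and combination libraries, HBB to 4026 and 23848 FPKM, and 10 of 11 tested markers were raised in combination vs DMSO under each of the 4 scalings. Against RNA carried into each library separately, HBB varied by at most 5.80% within a group (0.246% in the combination libraries). Against a single erythroid RNA source in differing shares, the ratio of combination to crenolanib ranged from 5.92 for HBB to 11.1 for HBM over abundant genes present in 1 copy, 1.88 times apart. Without HBB the ratios ran from 7.84 for ALAS2 (6.95 to 8.89 over the libraries) to 11.1 for HBM (10.8 to 11.7). These do not overlap, so the size of the gap rests largely on HBB, but not its presence. The 2 genes were picked as the extremes, so a single source is not excluded. HBA1 and HBA2 together reached at most 0.713% of HBB in the combination libraries, where red cells or their precursors would bring both chains, but how reads of identical copies were counted is not given in the sources used here, so red cell RNA and another source cannot be told apart by this value. A different source in each group and expression of these genes by the treated cells stay open as hypotheses.

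The combination libraries lacked transcripts of many genes and had a high mitochondrial share. Against depth as the whole cause, the DMSO libraries thinned to the same number of non-mitochondrial reads had a mean of 6230.5 genes at 0, 1575 fewer than the combination libraries (7805), over the 19839 non-mitochondrial genes of known length. Against transcript length, the fold changes in combination vs DMSO hardly followed gene length (rho 0.03 across genes). After this weak trend was removed, with the median shift of all genes kept, 97.0% of the genes lowered were still lowered. So weak a trend could change few calls, and this answer covers combination vs DMSO only. The trend was stronger in combination vs crenolanib (rho -0.16) and in the interaction (-0.21). There 96.4% and 94.2% of the lowered or negative genes kept their call. Of the raised or positive ones 849 of 975 and 1449 of 1717 did, and 10 and 9 of the 13 mitochondrially encoded genes. The combination libraries held a mean of 84 genes at 1 estimated read after rounding, 8.83% of the number in thinned DMSO libraries, which is consistent with few distinct molecules copied many times, as from little or damaged RNA. The crenolanib libraries, at their full depth, also held fewer such genes (290) than the DMSO libraries at theirs (657). Thinned to the depth of the combination libraries, they held 699 against 951 in thinned DMSO libraries. This cause was not tested for the crenolanib libraries. A loss of nuclear transcripts in dying cells stays open and was not tested, so the fall of a single gene in the combination may come from either.

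MAPK and FLT3-STAT5 output genes were lower in the libraries labelled HPA-12 than in those labelled crenolanib, although crenolanib is the FLT3 inhibitor: 18 of 28 members were lower and 0 higher. Of these 18, only 11 had also fallen with HPA-12 against DMSO. FOS, for 1, rose with HPA-12 (2.95) and rose more with crenolanib (4.60). Against scaling between libraries as the cause, at least 17 members were lower under each of the 4 scalings. The 18 members are the pattern itself and no separate test of an exchange of the HPA-12 and crenolanib labels, so exchanged and correct labels cannot be told apart from these values. A rebound of these genes at 48 h, the unknown doses and an effect of HPA-12 on the same pathway stay open and were not tested. If the labels were exchanged, the statements on the single agents would change hands, and combination vs crenolanib would trade places with combination vs HPA-12, while the interaction, which treats both agents alike, would not.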

How the results depend on the processing

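The 3 rescalings, 1 weight per group, the fit without the combination libraries and genes above 0 in all 12 libraries were chosen after seeing the data. Of 7087 results of named genes by setting, 7021 kept their side of the threshold, 48 no longer passed, 9 newly passed and 9 reversed. Some of the 7021 changed sign without passing in either, such as DDIT3 with crenolanib (0.22, and -0.27 without crenolanib library 2). Of 3214 results of lists by setting, fry left out, 3102 kept their side of the threshold, 63 no longer passed and 49 newly passed. An absolute log2 fold change over 1 left 1878 genes for HPA-12, 2053 for crenolanib, and for the combination 4595 against DMSO, 3300 against crenolanib and 4602 against HPA-12. A mean of at least 5 FPKM left 6231 genes to test, of which 3698, 4102, 5197, 5051 and 5134 passed in the same order and 4633 in the interaction. For HPA-12, a fit of the 2 compared groups only gave 8672 genes, one weight per group 8619 and the fit without the combination libraries 8136. For crenolanib the same settings gave 8415, 8522 and 8617. The first 2 settings lowered the combination counts, to 6904 and 6808 against DMSO, 5977 and 6085 against crenolanib, and 6916 and 6881 against HPA-12. In the simulations these 2 settings gave fewer false calls for the combination and also recovered fewer true changes. Median-ratio scaling gave 5112 genes for combination vs crenolanib. With replicate block the counts were 5539, 6150, 7907, 7749, 8009 and 7243, and libraries of the same number did not resemble each other (r -0.03 to 0.07).

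Leaving out 1 library at a time gave 4627 to 4931 genes and 13 to 15 lists for HPA-12, 5323 to 5573 and 11 for crenolanib, 7346 to 8292 and 8 to 10 for combination vs DMSO, 7091 to 8093 and 8 to 9 against crenolanib, 7474 to 8366 and 12 to 13 against HPA-12, and 6780 to 7894 and 14 to 15 for the interaction. Calls lost this way are given with the report's values, besides that of ribosomal protein genes with HPA-12, lost without DMSO library 2 (median 0.10, adjusted p = 0.089) or HPA-12 library 3 (0.11, adjusted p = 0.07).

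Median-ratio and upper-quartile scaling reversed 5 core gene results. In this order HSPA5 was at 0.36 and 0.47 against DMSO, ATF4 at 0.64 and 0.60 and XBP1 at 0.65 and 0.60 against crenolanib, and ATF4 at 0.48 and 0.51 against HPA-12, each with the combination. FLT3 in combination vs DMSO was at 0.11 under upper-quartile scaling, without passing.

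With an estimated correlation 7 lists passed for crenolanib, 6 for combination vs DMSO and 4 against crenolanib. With fry 23 lists passed for HPA-12, 26 for crenolanib, 27, 26 and 27 for the combination against DMSO, crenolanib and HPA-12, and 26 for the interaction. Camera compares a list with the other genes and fry does not, and their directions differed for the lists below, which passed with at least 1 of the 2 tests and are given with their medians. They were PERK-ATF4-CHOP (-0.24) and NRF2 (-0.29) with crenolanib, and monocyte (-0.39), interferon (-0.17), heat shock (-0.69) and NRF2 genes (-0.95) in combination vs DMSO. Against crenolanib they were PERK-ATF4-CHOP (-0.077), LXR (0.11), MAPK (-0.47), MYC (-0.44), DNA replication (-0.12), mitosis (-0.0093), p53 (-0.32), monocyte (-0.69), glycolysis (-0.63) and oxidative phosphorylation genes (-0.30). Against HPA-12 they were ATF6-branch (-0.43), IRE1-XBP1 (-0.30), cholesterol (-0.53), LXR (-0.066), DNA replication (0.050), p53 (-0.57), BCL2 (-0.65), monocyte (-0.24), glycolysis (-0.57), oxidative phosphorylation (-0.10), proteasome (-0.11) and NRF2 genes (-0.60). In the interaction they were IRE1-XBP1 (-0.63), PERK-ATF4-CHOP (-0.039), fatty acid (-0.45), LXR (-0.13), mitosis (-0.29), monocyte (-0.28) and NRF2 genes (-0.41). Directions also differed where neither test passed, for mitochondrially encoded genes with HPA-12 (0.018), IRE1-XBP1 with crenolanib (0.11), BCL2 genes in combination vs DMSO (-0.90) and mitosis genes in combination vs HPA-12 (-0.052). The cause of these and the other changes was not tested.

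A mean of at least 5 FPKM also ended calls of interferon genes with HPA-12 (adjusted p = 0.255), with crenolanib (0.771), in combination vs HPA-12 (0.335) and in the interaction (0.609), of MAPK genes with HPA-12 (0.204), and of MYC targets (0.124) and proteasome genes (0.15) in combination vs DMSO. For PERK-ATF4-CHOP genes this setting and no low-value filter gave adjusted p of 0.112 and 0.0972 in combination vs crenolanib and 0.0697 and 0.104 in combination vs HPA-12, and for DNA replication genes 0.11 and 0.151 in combination vs crenolanib.

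Some further lists passed only under an alternative, MAPK output in combination vs DMSO among them (median 0.46 and adjusted p = 0.00581 with a mean of at least 5 FPKM). With HPA-12 NF-kB genes passed with pseudocount 0.1 (adjusted p = 0.0318) and a mean of at least 5 FPKM (0.0168), erythroid markers with pseudocount 0.1 (0.0351) and without DMSO library 3 (0.0457), and mitosis (0.0438) and NRF2 genes (0.0235) with no low-value filter. NF-kB genes passed in the interaction with no low-value filter (0.0219), a mean of at least 5 FPKM (0.0423) and genes above 0 in all 12 libraries (0.0194).

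Planned edgeR, DESeq2 and voom fits with their normalizations and count filters were not run, since the table holds no counts. At 4.69 M estimated reads, genes of few reads are measured least well in the combination libraries, where a mean of 7971 genes were at 0.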

Other observations

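The genes in this part were chosen after their values were seen, and no hypothesis on them was tested. No gene list covers them as a group. JUN had 5.96 ± 0.135 FPKM in DMSO, 38.4 ± 2.23 with HPA-12, 391 ± 10.7 with crenolanib and 847 ± 48.5 with the combination, and FOS 7.31 ± 0.388, 63.1 ± 2.11, 200 ± 11.3 and 331 ± 12.95 FPKM in the same order. ATF3, a stress-induced transcription factor, had 1.35 ± 0.0783, 8.36 ± 0.493, 69.6 ± 2.24 and 108 ± 8.66 FPKM. GADD45B, a DNA damage response gene, had 16.9 ± 1.27 FPKM in DMSO, 15.5 ± 1.24 with HPA-12, 660 ± 32.3 with crenolanib and 1142 ± 80.9 with the combination. KLF6 did not follow this order, with 5.94 ± 0.625, 42.6 ± 2.06, 107 ± 1.66 and 42.2 ± 6.25 FPKM. It was lower with the combination than with crenolanib (-1.33, adjusted p = 6.6e-07). HPA-12 raised JUN (2.50), FOS (2.95) and ATF3 (1.99) and lowered EGR1 (-0.82).

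The next genes code for proteins of neutrophil granules. Elastase (ELANE) had 285 ± 23.5 FPKM in DMSO, 64.3 ± 3.55 with HPA-12, 234 ± 16.03 with crenolanib and 135 ± 20.2 with the combination, and cathepsin G (CTSG) 160 ± 7.34, 24.6 ± 2.20, 133 ± 6.77 and 240 ± 10.8 FPKM in the same order. Lysozyme (LYZ) had 399 ± 9.41, 86.9 ± 4.57, 357 ± 6.87 and 168 ± 14.1 FPKM. Azurocidin (AZU1) fell less with HPA-12 (-0.50, to 226 ± 11.1 from 320 ± 9.33 FPKM). With crenolanib ELANE (-0.28), CTSG (-0.27), LYZ (-0.16) and MPO (-0.18) fell and AZU1 (-0.06, adjusted p = 0.299) did not pass. Proteinase 3 (PRTN3) fell with each treatment, from 255 ± 13.4 to 68.6 ± 5.31, 84.3 ± 3.85 and 64.3 ± 13.4 FPKM.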
